A study of Macaca mulatta with 8 samples.

How the data were processed

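Gene expression was measured in epithelial cells isolated from the colon of rhesus macaques with chronic SIV infection and of control macaques, with 1 Agilent 1-colour (Cy3) array per labelled animal. The labels put 4 arrays in the control group and 4 in the SIV group. SIV animals received 100 TCID50 of SIVmac251 intravenously. The sample labels of the control arrays call them pre-infection, whereas the protocol describes uninfected control animals, and both descriptions were taken to mean animals without SIV. Per the file headers, the deposited intensity of each spot is the processed signal, that is the signal after background subtraction and detrending within the array, and no normalization between arrays had been applied. The submitters' processing notes name Agilent Feature Extraction 11.0.1.1. The deposited files also hold, per the file headers, 0 or 1 flags for other spot properties, namely well above background, positive and significant, saturated and outlier. A table of log2 values of the whole series was also deposited by the authors, on 36480 probes. How these were made is not given in the sources used here, but each column correlated at 0.998 or above with the log2 processed signal of its own array. The columns' medians lay between 8.73 and 8.74 and their maxima were equal, which is what quantile normalization gives. The values were not centred per gene.

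Each array held 45220 spots, of which 43803 were not control spots. They covered 43603 probes. Between 37 and 133 spots per array carried an outlier flag and were left out, and no spot was saturated. The spots of a probe were averaged. The log2 processed signal of each array was centred on that array's 75th percentile over all non-control probes, and a probe was tested if it was well above background on at least 4 of the 8 arrays, which left 37446 probes. Probe names came from the RefSeq accessions in the files, matched without versions to a table of the assembly T2T-MMU8v2.0. The table named 7096 probes, 6553 of them tested. No gene was named from the 21993 probes with Ensembl transcript identifiers, the 7447 with Agilent identifiers only or the 5649 with other accessions, so most of the array stayed unnamed. The array design was annotated on another assembly, rheMac2, per the file headers, and no coordinates are given. PPARG had a named probe. OCLN, the other gene of the study's title, had none and was not analysed here.

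Before averaging, arrays were compared over the probes well above background on all 8 arrays. Control arrays 1 and 2 differed with a robust SD of 0.139 on the log2 scale, and control arrays 3 and 4 with 0.121. Repeated spots of 30 probes within single arrays, 5 spots each, put the spread of 2 spots of the same RNA at 0.154 and 0.168 for these pairs. The other 26 pairs of arrays had robust SDs from 0.471 to 1.871. Both control pairs thus differed by less than the spread between repeated spots, although the labels give the arrays to different animals with different ages. The arrays of each pair were averaged and counted as 1 sample, named control A (arrays 1 and 2) and control B (arrays 3 and 4). The limit for calling a pair near-identical, a robust SD under 0.25, was set after these values were seen. The design fixed before the data were examined had counted 8 animals, 4 against 4. It was replaced by 2 control samples against 4 SIV samples for this reason, and the counts of the 8-array design are given beside the results. The labels do not say whether separate RNA preparations lie behind the arrays, so the p-values measure the spread between these 6 samples.

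The comparison of SIV with control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), per probe and per gene, with the tested probe of highest mean standing for a gene (4683 genes). Adjusted p-values are from limma with Benjamini-Hochberg adjustment, and the threshold was an adjusted p of 0.05. Single values were compared with an exact two-sided permutation test, which for 2 against 4 samples has 15 assignments and cannot go below p = 0.0667. A set of 43 gene lists of pathways, barrier genes, cell type markers and quality genes had been fixed before the data were examined. Lists were tested only in part, as with 19 of 46 interferon-stimulated genes, 8 of 30 tight junction genes and 27 of 36 ribosomal protein genes. The 26 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data and with fry, a rotation test of whether a list's genes move one way on balance. From set tests 35 genes with a missing value were left out. The rule for named genes, fixed before the data were examined, took PPARG and OCLN, then per direction the 15 genes of largest difference among those past the threshold whose SIV arrays all lay on one side of all control arrays. Free places went to the genes of smallest unadjusted p with the same separation. From each list it allowed up to 4 members by unadjusted p, and up to 3 more of highest mean signal from lists that mark another cell type or RNA quality. Genes named outside the rule are marked as chosen after their values were seen. Where no array of a group was well above background, a lower bound of the fold is given. It sets the mean of the brighter group against, per array, the higher of the dim probe's own value and the lowest signal among probes well above background.

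The fit was tested on simulated data for the comparison of SIV with control at 4 and 2 samples, with 200 changed features in each of 20 runs. Among 4683 genes, 1.9% of genes changed 2-fold passed the threshold, 24.4% of those changed 4-fold, 78.8% of those changed 8-fold and 95.7% of those changed 16-fold. Among 37446 probes the shares were 0.0%, 1.7%, 26.7% and 74.2%. With no simulated difference, 4.9% of 4683 genes had an unadjusted p below 0.05 when near-identical control arrays were averaged, and 14.7% when they were counted as separate animals. The list test found an interferon list shifted by 1 on the log2 scale in 20 of 20 runs, and called 0 of 520 lists in runs without a shift. These simulated genes were independent, which real genes of a list are not.

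Alternatives fixed before the data were examined were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization alone, centring on the median, the deposited log2 table, no filter on dim probes or a stricter one, age as a covariate, array weights, a trended robust variance, the mean over a gene's probes, and leaving out each array. The mean signal planned for normexp was replaced by the median signal of the spot, which the files used here give. For age as a covariate, control A and control B each took the mean of the labelled ages of their arrays. If the arrays of a pair hold the same RNA, this mean may be the age of no animal, which limits every age-adjusted value. Alternatives added after seeing the data were the 8-array design, the near-identical arrays as a random block, leaving out each control sample, and leaving out SIV 4 with an estimated correlation. All 4 SIV arrays lay on 1 slide and all 4 control arrays on another, so slide and group cannot be told apart. The number of arrays limits the precision of every value.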

Results

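Transcript levels were measured on arrays in colonic epithelium of rhesus macaques, a model host of the simian immunodeficiency virus (SIV), which causes an AIDS-like disease in this species. The 8 arrays were labelled as 4 chronically infected animals and 4 controls. Signal was well above background for 33033 to 37059 probes on the control arrays and for 36130 to 38606 on the SIV arrays. With near-identical arrays averaged, the mean was 37760 ± 1140 (SD, n = 4) in SIV and 35740 ± 1850 (SD, n = 2) in control, a difference of 2024 (exact two-sided permutation p = 0.2, 15 assignments). The 75th percentile of the processed signal was 1220 to 1307 on the control arrays and 1856 to 2459 on SIV arrays 1, 2 and 3, but 675.7 on SIV 4, the dimmest array. Group means differed by 520.7 (exact permutation p = 0.4000). By the labels, SIV animals were 5.035 ± 1.62 years old (SD, n = 4) and control animals 6.13 ± 0.426 years (SD, n = 4), an exact permutation p of 0.3143 over 70 assignments.

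Control arrays 1 and 2 differed by less than the spread between repeated spots of an array, and so did control arrays 3 and 4. Each pair was therefore counted as 1 sample (control A and control B), and the comparisons set 4 SIV samples against 2 control samples. The plan fixed before the data were seen had set 4 control animals against 4 SIV animals. Pearson's r across probes was at least 0.995 within these pairs. SIV 4 had r from 0.799 to 0.867 with every other array, and the remaining pairs had r from 0.928 to 0.973, where probes are not independent replicates.

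**Figure D1:**
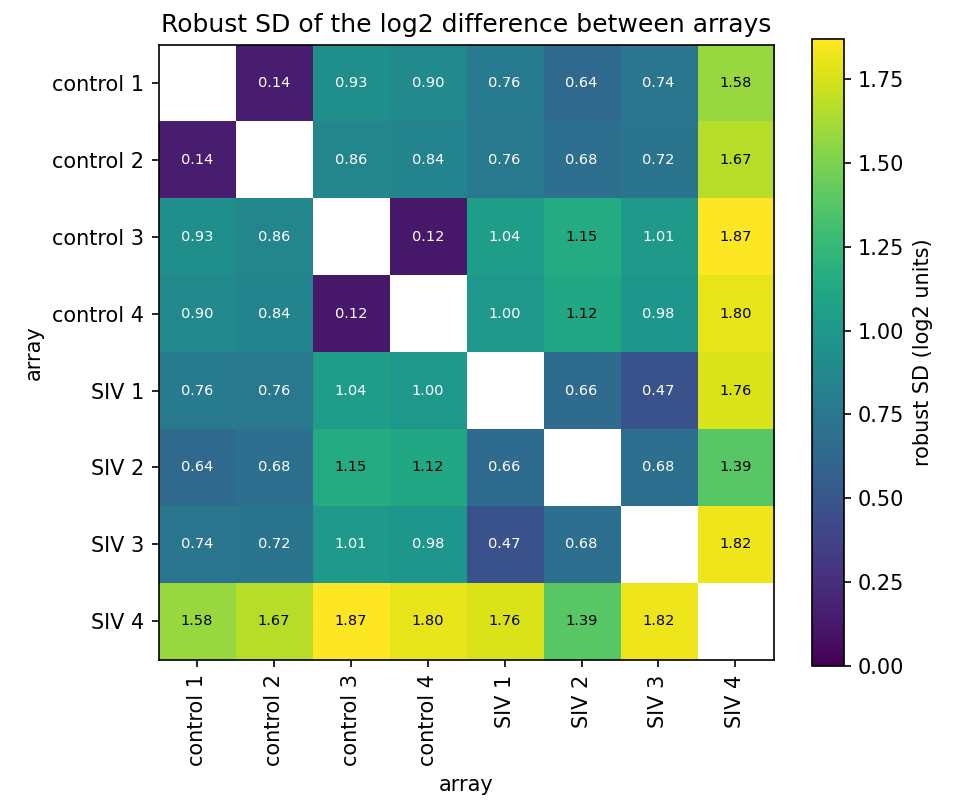
Robust SD of the log2 difference (log2 units, colour and number) between each 2 of the 8 arrays, over probes well above background on all of them. Control arrays 1 and 2 (0.139) and 3 and 4 (0.121) lie far below the other pairs (0.471 to 1.871), and the pairs of SIV 4 are the most distant.

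The study's title names PPARG, a nuclear receptor that directs lipid metabolism and epithelial differentiation in the colon, and occludin. PPARG (RefSeq NM_001032860) was lower in the SIV samples by a log2 difference of -1.37 (SE 0.60), with 1.11 ± 0.64 (SD, n = 4) in SIV and 2.49 ± 0.92 (SD, n = 2) in control, on the scale of log2 signal relative to the array's 75th percentile. All 4 SIV samples lay below both control samples, at 0.253 to 1.744 against 1.836 and 3.142. The difference did not pass the test (limma adjusted p = 0.922, exact two-sided permutation p = 0.1333 over 15 assignments). Counted as 4 against 4 arrays, the adjusted p from limma was 0.205 and the exact permutation p was 0.0286 over 70 assignments. That count treats near-identical control arrays as separate animals. Without control sample B the log2 difference was -0.72, and without control sample A it was -2.03. OCLN was not analysed here.

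Among genes whose SIV arrays all lay on one side of all control arrays, those of smallest unadjusted p included SERPINH1, a collagen chaperone, PNP, a purine salvage enzyme, and MX1 and TRIM5, antiviral restriction factors, which were all higher in SIV. SERPINH1 was higher by 2.88 (SE 0.57) on the log2 scale, PNP by 2.25 (SE 0.48), MX1 by 2.82 (SE 0.62) and TRIM5 by 2.39 (SE 0.58), with n = 4 SIV and n = 2 control samples. On the lower side stood CHN2, a Rac GTPase-activating protein, with a log2 difference of -2.37 (SE 0.44), EDNRA, the endothelin A receptor, with -3.02 (SE 0.61), PLSCR4 with -2.42 (SE 0.49) and CFTR, the apical chloride channel, with -2.31 (SE 0.51). None of these passed the test over all 4683 genes (limma adjusted p = 0.801 for each). With the mean over the probes of a gene, TRIM5 was at 1.19 and PLSCR4 at -1.50.

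In limma, 0 of 37446 probes and 0 of 4683 genes passed. At an unadjusted p below 0.05 there were 2054 probes, 1208 higher and 846 lower in SIV, where 1872 would be expected with no difference. There were 252 such genes, 133 higher and 119 lower, where 234 would be expected. These counts depend on single samples, with 4659 probes and 580 genes without SIV 4, 1253 and 151 without SIV 2, and 952 and 106 without control sample B. Of 4648 genes with a value in all samples, 798 (17.2%) had all 4 SIV samples on one side of both control samples, 459 higher and 339 lower, and chance gives 13.3%. The median log2 difference of all tested probes was 0.09. Counting the 8 arrays as 8 animals gave 31 probes, 14 of them higher, and 16 genes, with 6213 probes and 694 genes at an unadjusted p below 0.05. With no simulated difference, this count had put 14.7% of 4683 genes at an unadjusted limma p below 0.05, so the 694 genes are near what no difference gives. The 16 genes were 7 higher (SERPINH1, PNP, MX1, SBK2, COQ10B, MIC1 and MICB) and 9 lower (CHN2, PKDREJ, PLSCR4, CFTR, EDNRA, ELAPOR2, PRCP, SFRP4 and EDIL3). EDIL3, with a log2 difference of -2.83, lay outside the rule for named genes and was named after its value was seen. Without SIV 4, limma called 7 probes, 2 of them higher, and 0 genes.

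The other genes named by the rule were likewise short of the threshold, each with an adjusted p of 0.801 in limma. Higher in SIV were MNP2 by 2.61 (SE 0.71; 1.61 without control sample A) and the olfactory receptor OR10P1 by 2.18 (SE 0.61). WDR38, TMEM74, COQ10B, SBK2, HAS3 (a hyaluronan synthase) and ZBTB45 were higher by 1.97, 1.92, 1.89, 1.86, 1.72 and 1.66. MICB and MIC1, MHC class I-related genes of near-identical sequence whose probes may not tell them apart, were higher by 1.81 and 1.74. NTRK2 was at least 1.72-fold higher, since no control array was well above background. Lower in SIV were ELAPOR2, an endosomal and lysosomal membrane protein, by a log2 difference of -3.15 (SE 0.71), JAKMIP2 of -3.04 (SE 0.82) and DYNC1I1, a dynein subunit, of -2.78 (SE 0.76). The muscarinic receptor CHRM3 had -2.44, PKDREJ -2.17, the transcriptional repressor HBP1 -2.09, the Wnt antagonist SFRP4 -2.01, PPP2R3A -1.98, the peptidase PRCP -1.87 and the lysosomal galactosidase GALC -1.84. EFHD1 was at least 2.38-fold lower, since no SIV array was well above background. With normexp background correction and quantile normalization many of these differences were far smaller. They were -1.22 for ELAPOR2, -0.40 for JAKMIP2, -0.97 for DYNC1I1, -0.45 for PKDREJ, -0.36 for SFRP4 and -0.28 for EFHD1, and on the higher side 0.59 for MICB, 0.57 for MIC1, 0.54 for WDR38, 0.29 for TMEM74, 0.14 for NTRK2, 1.09 for HAS3, 1.06 for ZBTB45 and 1.53 for MNP2. The lower bounds of the fold for NTRK2 and EFHD1 hold only for the processed signal. With the mean over probes CHRM3 was at -1.57. JAKMIP2 was well above background on 1 of the 4 SIV arrays, PKDREJ and DYNC1I1 on 2, and SFRP4 on 3, and TMEM74 was so on 1 of the 4 control arrays.

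**Figure D2:**
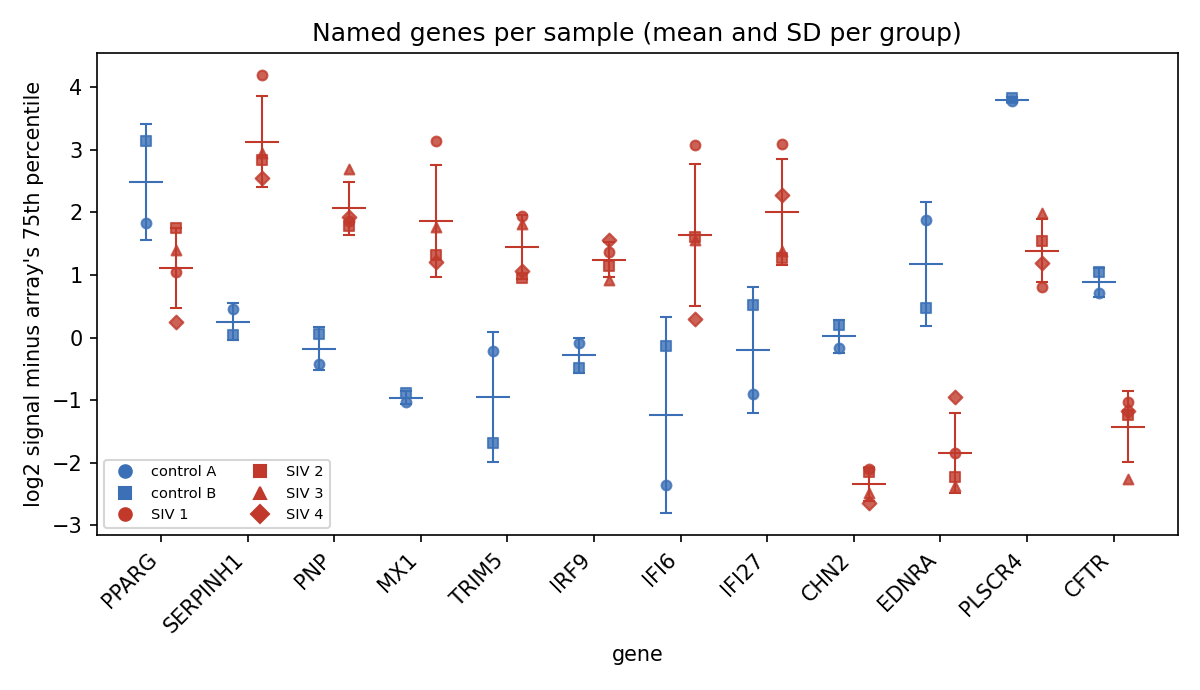
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 named genes in control samples A and B (blue) and 4 SIV samples (red), with bars for the mean and SD of each group. The SIV and control values of MX1, CFTR and PPARG do not overlap, with log2 differences of 2.82, -2.31 and -1.37. For MX1 and CFTR the rule for named genes required this.

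Interferon-stimulated genes, which respond to viral infection through type I interferon, were higher as a group in the SIV samples. Of 19 tested members, 14 were higher and 5 lower, with a median log2 difference of 0.62. MX1 and TRIM5 are given above. IFI6 was higher by 2.88 (SE 0.86), IFI27 by 2.20 (SE 0.67) and IRF9, a transcription factor of the interferon response, by 1.53 (SE 0.44). These 5 genes passed when adjusted over the list alone (limma adjusted p from 0.028 to 0.0403), and 0 passed over all genes. None of the 5 passed over the list alone without SIV 3 or without control sample A or B, only MX1 did without SIV 1, only MX1 and TRIM5 did without SIV 2, and without SIV 4 all 5 did among 8 members. IFI6 was at 1.77 without control sample A. IFI27 lay outside the rule for named genes and was named after its value was seen. The list passed camera with the preset correlation (adjusted p = 0.00584), but not with an estimated correlation (adjusted p = 0.803 with an estimated correlation). The median of its members, relative to the control mean, was 1.53, 0.69 and 1.08 in SIV 1, 2 and 3 and -0.32 in SIV 4, and the median log2 difference was 0.96 without SIV 4, 0.32 without SIV 1, 0.24 without control sample A and 0.94 without control sample B. The call was lost without SIV 1 (adjusted p = 0.0543), without control sample A (0.265) and with age as a covariate (0.232). The list of interferon-gamma responses had 6 of 12 members higher and 6 lower (camera adjusted p = 0.795, and 0.0246 and higher without control sample B). Its members CXCL10 and CXCL11, T cell chemoattractants, had log2 differences of 1.44 (SE 1.26) and 1.27 (SE 1.25), which rest on control sample A, since they were -1.0 and -0.67 without it and 3.87 and 3.22 without control sample B. Without SIV 2 CXCL11 was at 2.07.

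T and NK cell markers were lower as a group. Of 9 tested members, from a list of 28 genes, 7 were lower and 2 higher, with a median log2 difference of -1.98. GZMK, a granzyme, had a log2 difference of -3.27 (SE 1.42), the NK receptor KLRD1 -2.91 (SE 1.03) and CD2 -2.48 (SE 1.11). Of the higher members, CD4 was at least 1.52-fold higher in the processed signal, since no control array was well above background. Its log2 difference was 1.17, and 0.40 without control sample B. IL2RB was higher by 0.71 (SE 0.61; 0.29 without SIV 4). CD4 and IL2RB lay outside the rule for named genes and were named after their values were seen. No member passed when adjusted over the list alone (smallest limma adjusted p = 0.105), but 7 did without SIV 3, GZMK, KLRD1 and CD2 among them, and 3 without SIV 4. The list passed camera with the preset correlation (adjusted p = 0.00584, and 0.803 with an estimated correlation). Its median was -3.09 and -3.14 in SIV 1 and 2, -0.05 in SIV 3 and -1.17 in SIV 4, and without control sample A the adjusted p was 0.201. Macrophage markers did not pass, with 7 of 13 members higher and 6 lower and a median of 0.06 (camera adjusted p = 0.693), nor did B and plasma cell markers, with 3 of 6 higher and a median of 0.01 (adjusted p = 0.685), whose mean of -0.06 and camera direction were lower. With 1 sample left out these medians changed sign, the macrophage one from -0.23 (without SIV 3) to 0.46 (without SIV 2 or control sample B), and the B and plasma cell one from -0.15 (without SIV 1) to 0.25 (without SIV 2). Among the latter JCHAIN, which joins polymeric immunoglobulins, had a log2 difference of -1.37 (SE 0.58).

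Genes of ion and water transport, which drive fluid handling in the colon, were lower, with 7 of 9 tested members lower, 2 higher and a median log2 difference of -1.17. The guanylin-family peptide GUCA2B had -2.92 (SE 1.15), CFTR -2.31 (SE 0.51), the carbonic anhydrase CA2 -1.76 (SE 0.76) and the chloride cotransporter SLC12A2 -0.91 (SE 0.54). Only CFTR passed when adjusted over the list alone (limma adjusted p = 0.0156), and it did not without control sample A or B, while without SIV 2 GUCA2B passed too. SLC12A2 was at -0.51 without control sample A. The list passed camera (adjusted p = 0.0073, and 0.803 with an estimated correlation), but not without SIV 4 (0.0627), without control sample A (0.201) or with array weights (0.07). The median of these genes in SIV 4 was -2.05, against -0.61 to -0.37 in the other SIV samples, the median log2 difference without SIV 4 was -0.63, and markers of epithelium in general had a median of -1.94 in SIV 4.

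Ribosomal protein genes were slightly lower, with 26 of 27 tested members lower and a median log2 difference of -0.33, against a median of 0.09 over all probes. RPLP0 had -0.85 (SE 0.43) and RPS14 -0.61 (SE 0.49), and no member passed when adjusted over the list alone (smallest limma adjusted p = 0.816). The list passed camera (adjusted p = 0.0105, and 0.803 with an estimated correlation). It did not pass after quantile normalization (adjusted p = 0.227), in the deposited log2 table (0.233), with age as a covariate (0.148), without SIV 1 (0.138), without SIV 2 (0.0624) or without control sample A (0.201). Relative to the control mean, the median was -0.61 and -0.56 in SIV 1 and 2, -0.08 in SIV 3 and 0.09 in SIV 4, and the median log2 difference was -0.21 without SIV 1.

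Genes of the unfolded protein response, the reaction to misfolded protein in the endoplasmic reticulum, were higher, with 8 of 10 tested members higher and 2 lower and a median log2 difference of 0.67 (0.44 without SIV 3). The transcription factor DDIT3 was higher by 1.59 (SE 0.50), the chaperone HSPA5 by 1.06 (SE 0.49) and CALR by 1.44 (SE 0.83; 0.80 without SIV 4, 0.84 without control sample B), and no member passed when adjusted over the list alone (smallest limma adjusted p = 0.127), but 3 did without SIV 4, DDIT3 and HSPA5 among them. Cholesterol synthesis genes were higher too, with 6 of 7 higher and a median of 0.42 (0.74 without control sample A, 0.90 without control sample B). STARD4, a sterol carrier, was higher by 1.04 (SE 0.52), and no member passed when adjusted over the list alone (smallest limma adjusted p = 0.0533), but 1 did without SIV 3, without SIV 4 and without control sample A. Genes of fatty acid oxidation were lower, with 8 of 9 lower and a median of -0.49. HADH had a log2 difference of -1.37 (SE 0.44) and ACAT1 -0.79 (SE 0.44; -0.44 without control sample B), with no member past the threshold adjusted over the list alone (smallest limma adjusted p = 0.13). These lists passed camera with adjusted p of 0.0349, 0.0349 and 0.0358, and had an adjusted p of 0.803 with an estimated correlation. Without control sample A the values were 0.265, 0.295 and 0.197, without SIV 4 they were 0.016, 0.136 and 0.0973, and without SIV 1 they were 0.138, 0.0543 and 0.138. With age as a covariate they were 0.298, 0.0593 and 0.292. The unfolded protein response also lost the call with the mean over probes (0.0691) and without SIV 3 (0.0817), and cholesterol synthesis with array weights (0.135), without SIV 2 (0.0733) and with 8 arrays as 8 animals (0.0529). Fatty acid oxidation lost it after quantile normalization (0.0687), in the deposited log2 table (0.0729), with array weights (0.0537), without SIV 3 (0.0817) and without control sample B (0.114).

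**Figure D3:**
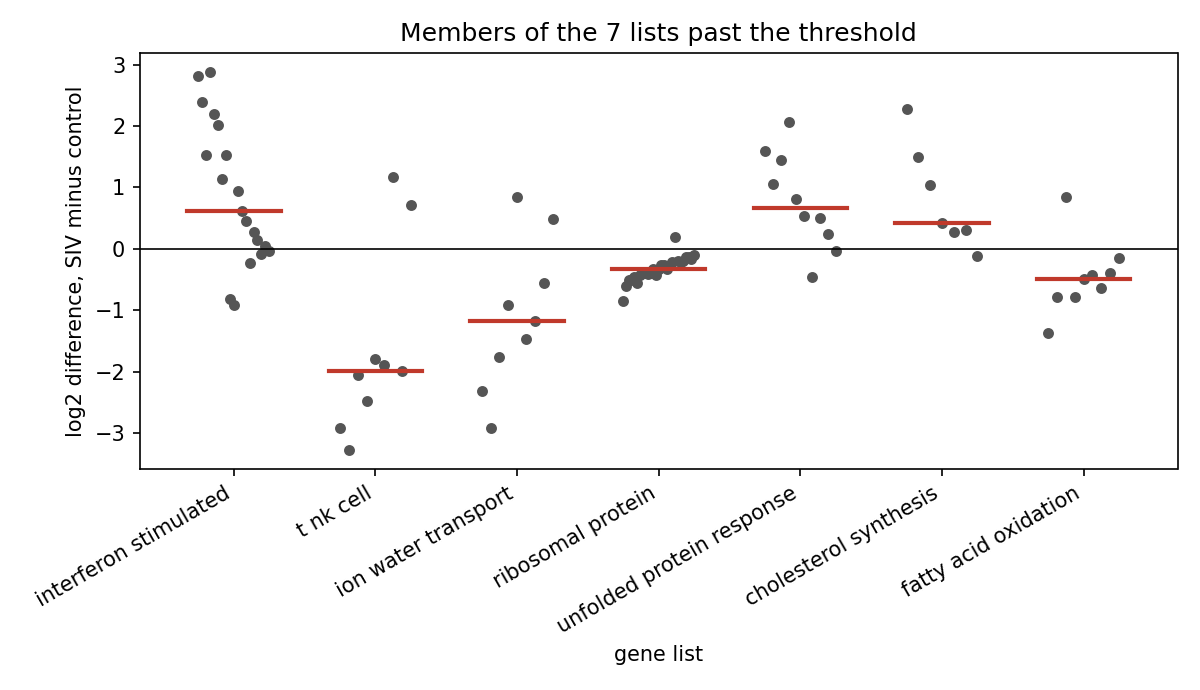
Log2 difference between SIV and control samples (vertical axis) of each tested member (points) of the 7 gene lists past the threshold, with the red line at the list median. Medians run from -1.98 for T and NK cell markers to 0.67 for the unfolded protein response, and members of the ribosomal list lie close to their median of -0.33.

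In all, 7 of 26 tested lists passed camera with the preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.803) or with fry (smallest adjusted p = 0.501). At an unadjusted p below 0.05, limma gave 5 members of the interferon list, 3 of ion and water transport, 2 of the T and NK list, 1 each of the unfolded protein response, cholesterol synthesis and fatty acid oxidation lists, and 0 ribosomal ones. Slide and group cannot be told apart for any of them.

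Tight junction genes, which seal the paracellular route, did not pass (camera adjusted p = 0.571). Of 8 tested members 5 were lower and 3 higher, with a median of -0.25. The claudins CLDN3 and CLDN8 had log2 differences of -0.62 (SE 0.46) and -0.75 (SE 0.58), and F11R, a junctional adhesion molecule, had -0.79 (SE 0.64). Without SIV 4 the median of the list was 0.11 and F11R was at -0.37. The list median was -0.46 without SIV 2 and -0.09 without control sample B. CLDN8 was at -1.39 without control sample A and -0.11 without B, and CLDN3 at -0.31 without A. PPAR target genes had 4 of 6 members lower and a median of -0.56 (adjusted p = 0.396), among them the fatty acid carriers CD36 with -1.76 (SE 1.01; -0.94 without SIV 4) and FABP4 with -1.33 (SE 1.01). FABP4 was at -2.00 without SIV 4, -0.76 without SIV 1, -2.40 without control sample A and -0.25 without B, and the median of the list was -0.31 without B. Nuclear receptors had 4 of 7 lower (adjusted p = 0.693). Adherens junction genes, with 4 tested, were not tested as a list, and CTNND1 and CTNNA1 had log2 differences of -0.93 (SE 0.60) and -0.84 (SE 0.55). These were -0.73 and -0.52 without SIV 4, -1.76 and -1.16 without control sample A, and -0.11 and -0.53 without B.

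Of the remaining lists, xenobiotic metabolism had 8 of 10 members lower (camera adjusted p = 0.189), including SULT1B1 with -1.64 (SE 0.57) and UGT1A1 with -1.54 (SE 0.67; -1.02 without control sample B), while GSTA1 was higher by 1.66 (SE 0.71). Oxidative phosphorylation had 17 of 21 lower (adjusted p = 0.387). The oxidative stress list had 14 of 18 higher (0.571), with SRXN1 at 1.38 (SE 0.59) and GPX2 at 1.27 (SE 0.55). Antigen presentation had 8 of 11 lower (0.571). Nutrient and bile transport had 6 of 9 lower (0.571, and 0.0354 without SIV 2), with the efflux pump ABCB1 at -3.54 (SE 1.26) and the butyrate carrier SLC16A1 at -1.39 (SE 0.70). Glycolysis and hypoxia had 8 of 9 higher (0.653), dissociation stress 9 of 14 higher (0.685) and proliferation 7 of 11 higher (0.685). NF-kB and inflammation had 12 of 21 lower (0.693), with its inhibitor TNFAIP3 at -1.74 (SE 0.62). Antimicrobial genes had 6 of 11 higher (0.693, and 0.0246 without control sample B), with the elastase inhibitor PI3 at 1.21 (SE 0.48), and apoptosis genes had 5 of 7 higher (0.693). Enteroendocrine markers had 3 of 5 higher (0.693), with a median of 0.16 (-0.22 without SIV 4, -0.21 and -0.32 without control sample A or B), while the mean was -0.02 and camera's direction was lower. TGF-beta and fibrosis genes had 6 of 9 lower (0.693), with a median of -0.45 (-0.27 without SIV 4, 0.00 without control sample A), a mean of 0.08 and a lower direction in camera, and SMAD3 in this list was higher by 2.22 (SE 0.70). Over these lists, 0 members passed when adjusted over the list alone. Without SIV 4, 2 members each of proliferation and TGF-beta genes and 1 each of antimicrobial and apoptosis genes did. So did 2 members of nutrient and bile transport without SIV 2, 1 of NF-kB and inflammation without SIV 3 and 1 of TGF-beta genes without control sample A.

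**Figure D4:**
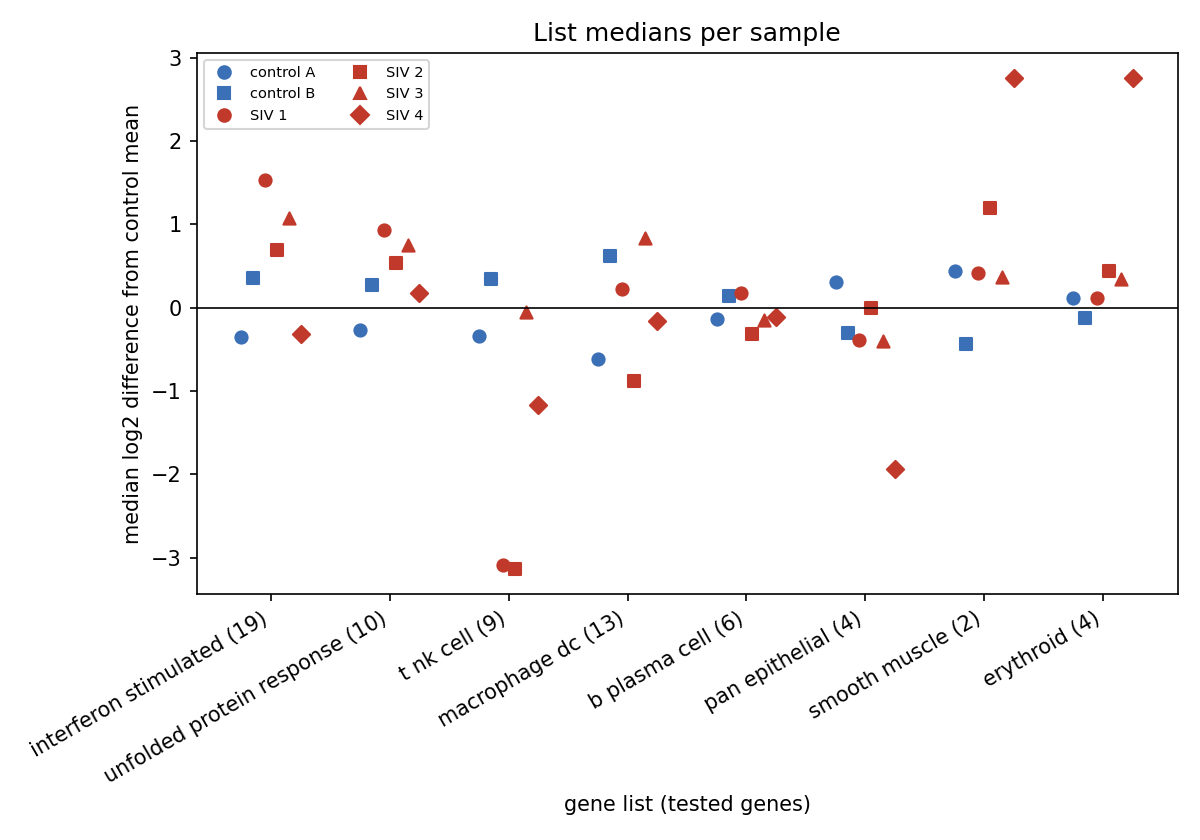
Median over the tested members of each list (number in brackets) of the log2 difference from the control mean (vertical axis), for control samples A and B (blue) and each SIV sample (red). T and NK markers are at -3.09 and -3.14 in SIV 1 and SIV 2, and SIV 4 stands apart in epithelial (-1.94), smooth muscle (2.75) and erythroid (2.76) markers.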

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

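The tests on neighbouring positions, on the brightest probes, on the marker lists, on immune cell types, on slides and on the splits were chosen after the result was seen. In 78 sets of 4 SIV values, 8 had a sample whose gap to its neighbour exceeded the 95% limit of Dixon's test, and chance gives about 1 in 20, or 3.9. Among genes, SIV 3 stood apart for PNP (2.70 against 1.78 to 1.92), MIC1 (-4.24 against -3.57 to -3.48) and CFTR (-2.27 against -1.24 to -1.03). Among list medians relative to the control mean, SIV 4 stood apart for erythroid markers (2.76 against 0.12 to 0.44), ion and water transport (-2.05 against -0.61 to -0.37) and Notch and differentiation genes (-1.83 against -0.21 to 0.12). SIV 3 stood apart for oxidative phosphorylation (0.12 against -0.31 to -0.26), and SIV 2 for PPAR targets (-0.39 against -0.36 in the other 3 samples).

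Control arrays 1 and 2, and control arrays 3 and 4, were near-identical. Over the 1000 probes that varied most between SIV 1, 2 and 3, with ranges of at least 2.42 on the log2 scale, the robust SD within the control pairs was at most 0.164, against 0.891 or more between control arrays of different pairs. At most 6 of these probes differed over 2-fold within a pair, against at least 324 between pairs, which argues against 2 different animals in each pair. Neighbouring positions on a slide are argued against too, since SIV 1 and SIV 2, in the same positions as control arrays 1 and 2, had a robust SD of 0.655. The same RNA on both arrays of a pair may account for the pattern, and no label settles where it would have happened.

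SIV 4 stood apart from all other arrays. Over the 7863 brightest probes its median robust SD against the other SIV arrays was 1.566, where pairs of SIV 1, 2 and 3 reached 0.530, so noise of dim spots alone is unlikely. Between 2 probes of the same gene, the deviation of SIV 4 from the other SIV arrays correlated at r = 0.47 across 1395 genes, below the 0.5 set in advance to exclude probe noise, so how much is noise stays open. Fewer epithelial cells with every other type raised alike would put all other marker lists higher in SIV 4. Fibroblast markers (-0.97, SE over genes 0.47, 3 of 4 lower) and macrophage markers (-0.90, 7 of 13 lower) were lower. B and plasma cell markers were at -0.16. T and NK (1.32), mast cell and eosinophil (1.41), erythroid (1.80) and smooth muscle markers (2.09, SE 0.17, 2 genes) were higher. Among lists of 3 genes, endothelial (-1.39) and neutrophil markers (-1.14) were lower, and neuronal and glial markers (2.06) were higher. These values come from a single array and few genes, so they argue only weakly against that explanation. More muscle in this sample, degraded RNA or disease in this animal were not tested.

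T and NK cell markers were lower in the SIV samples. The median of macrophage markers lay 2.04 above that of T and NK markers, with standard errors over members of 0.25 and 0.51. These errors are over genes and leave out the spread between animals. Per sample, macrophage medians were 0.22, -0.88, 0.84 and -0.16 in SIV 1 to 4, and -0.62 and 0.62 in control samples A and B. Each SIV value lay above the T and NK median of its sample. For these 2 lists this argues against a loss of all immune cells alike, within the wide spread of the control samples. Slide stays open, since 0 slides held both groups, and a difference between slides cannot be told apart from the infection. Fewer T and NK cells among the cells isolated from the SIV animals, or lower transcript levels in them, may account for it. Neither was tested. However, the pattern rests on SIV 1, 2 and 4, with -0.05 in SIV 3, and 2 of the 9 members, CD4 and IL2RB, were higher.

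Counting 8 arrays as 8 animals, limma called 16 genes. Splits that part near-identical arrays put near-identical values on both sides, and none of these 28 splits called a gene. Of the 7 splits of the 8 arrays that keep both pairs together, 1 gave as many genes, the real one, and the highest other gave 15. With 7 splits no share under 0.05 can be reached. The test had first been set over all 35 splits and was limited to these 7 after the counts were seen.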

How the results depend on the processing

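Averaging near-identical control arrays was decided after the arrays had been compared, so the planned count of 8 arrays as 8 animals stands here as an alternative. The random block, the control samples left out and SIV 4 left out with an estimated correlation were chosen after seeing the data. No paired analysis was possible because the labels name different animals in the groups and link no SIV array to a control array, and the array numbers used here only give their order. Probes past the threshold, 0 in limma with 2054 at an unadjusted p below 0.05, numbered 1 with normexp and quantile normalization together, 6 with array weights (1 higher), 31 with 8 arrays as 8 animals and 1 with a random block, and 0 to 7 when single arrays were left out, with 7 without SIV 4. Genes past the threshold, 0 with 252 at an unadjusted p below 0.05, numbered 16 with 8 arrays as 8 animals and 0 in the other alternatives. The counts at an unadjusted p below 0.05 moved by over 1.5 times with array weights (3923 probes, 400 genes), 8 arrays as 8 animals (6213, 694), without SIV 4 (4659, 580), without SIV 2 (1253, 151) and without control sample B (952, 106). Lists past the threshold, 7, numbered 2 with age as a covariate, 4 with array weights, 0 with an estimated correlation, 0 with fry, 0 without SIV 4 with an estimated correlation, 0 without control sample A, and 2 to 7 when single arrays were left out, with 2 without SIV 1 and 4 without SIV 4. Without control sample B, 8 lists passed. In the fits without A or B the lone control sample is assumed to vary like the SIV samples. Of 147 values of the 7 lists under alternatives, 113 were past the threshold in the same direction and 34 were not past it. These values are all from camera with the preset correlation, and none of the 7 lists was past the threshold with an estimated correlation or with fry. They include the fits without 1 array of a near-identical control pair, which change the data little. All 7 lists passed in each of those fits, so the tally overstates how far the calls hold. Of 399 values of the other lists, 3 were past it (interferon-gamma responses and antimicrobial genes, both higher with 0.0246 without control B, and nutrient and bile transport, lower with 0.0354 without SIV 2) and 20 turned direction with neither value past it. These 20 had adjusted p as follows. Interferon-gamma responses had 0.972 (normexp and quantile normalization), 0.769 (age), 0.974 (without SIV 1), 0.876 (without SIV 3) and 0.267 (without control A). Macrophage markers had 0.769 (age), 0.876 (without SIV 3) and 0.811 (without control A). Proliferation had 0.842 (age) and 0.796 (without control A), TGF-beta genes 0.692 (no filter) and 0.816 (without control A). Nuclear receptors had 0.981 (array weights) and 0.877 (without SIV 4), enteroendocrine markers 0.876 (without SIV 3) and 0.872 (without control A). Antimicrobial genes had 0.424 without control A. Without control B, dissociation stress had 0.392, NF-kB genes 0.281 and oxidative phosphorylation 0.642. When single arrays were left out, adjusted p ran from 0.562 to 0.974 for interferon-gamma responses, 0.302 to 0.887 for macrophage markers, 0.562 to 0.876 for enteroendocrine markers and 0.665 to 0.877 for nuclear receptors. The cause of these changes was not tested. PPARG kept its direction in all 22 alternatives, at -2.03 to -0.72 with adjusted p from 0.205 to 1, and the other 30 named genes in all 651 values, of which 15 were past the threshold, all with 8 arrays as 8 animals. The rule had taken these 30 genes because all their SIV arrays lay on one side of all control arrays, which also held for PPARG. Leaving out arrays or samples, or counting 8 arrays as 8 animals, could therefore not turn their direction. Size was not kept, since 14 of these 30 genes moved by over 1.5 times with normexp and quantile normalization together, on the median spot signal, all to smaller values. So did 3 with the mean over probes and 1 without control sample A. The share of higher probes among those past the threshold has no value, since 0 passed. A slide block was not run, because each slide holds 1 group. OCLN has no value. Signal over background limits probes near the floor, and SIV 4 had the lowest median signal over local background, 5.462, against 7.87 to 14.48 on the other arrays.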

Other observations

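Values of lists with fewer than 5 tested genes were not tested as lists and belong to no comparison above. CLCA1, a secreted protein of goblet cells, had a log2 difference of -1.57 (SE 0.51), while AGR2, another goblet cell gene, had 0.47 (SE 0.69; 0.07 without SIV 4, -0.35 without control sample A, 1.30 without B), and these are the same 2 genes in the lists of goblet markers and of mucin secretion. Mature colonocyte markers GUCA2B and TMIGD1 had -2.92 (SE 1.15) and -2.84 (SE 1.28), with a list median of -0.17 in SIV 2 and -5.25 in SIV 1. Among stem cell and Wnt genes, PROM1 had -3.41 (SE 1.0) and LGR5 had -0.99 (SE 0.51; -0.47 without control sample A, -1.51 without B). The mast cell receptor KIT had -2.17 (SE 0.74). Of the hemoglobin genes, HBA had 2.58 (SE 0.78), HBB 1.02 (SE 1.15), HBM 0.66 (SE 0.62) and the brighter HBA1 -0.07 (SE 0.58), and without SIV 4 they had 2.03, 0.08, 0.31 and -0.38. HBB was at 1.54 without SIV 1, 0.16 without control sample A and 1.87 without B, HBM at 1.04 without SIV 2, and HBA1 ran from -0.43 (without control B) to 0.29 (without control A). ACTA2, smooth muscle actin, had 1.59 (SE 0.70). Limma adjusted p over all genes was at least 0.801 for each of these genes. Adjusted over the list alone, CLCA1 (limma adjusted p = 0.0274), PROM1 (0.0339) and HBA (0.0404) passed. None of them did without control sample A or B, HBA did not without SIV 1 or SIV 2, and CLCA1 did not without SIV 2 or SIV 3. GUCA2B and TMIGD1 passed without SIV 2 and without SIV 4, and KIT without SIV 4.

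In the other small lists, EPCAM of the pan-epithelial markers had -0.80 (SE 0.52), GNG13 of the tuft markers -0.73 (SE 1.06), PRSS2 of the Paneth and small intestine markers 0.72 (SE 0.76) and KLF4 of the Notch and differentiation genes -0.62 (SE 0.64). COL3A1 of the fibroblast markers had -1.48 (SE 0.91), VWF of the endothelial markers -0.98 (SE 0.66), CXCR1 of the neutrophil markers 0.94 (SE 0.70) and SNAP25 of the neuronal and glial markers -0.62 (SE 0.49). Single samples carry many of these values. Without SIV 4, EPCAM was at -0.49, GNG13 at -1.51, PRSS2 at 0.21, KLF4 at -0.22, COL3A1 at -0.93, VWF at -0.63 and CXCR1 at 0.54. Without SIV 3, PRSS2 was at 1.17 and GNG13 at 0.00. Without control sample A, KLF4 was at -0.11, COL3A1 at -0.12, VWF at -0.14, GNG13 at -0.47 and SNAP25 at -0.35. Without control sample B, KLF4 was at -1.13, COL3A1 at -2.84, VWF at -1.82 and CXCR1 at 0.55. The list of mesothelial and squamous markers had 0 tested genes.

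Of 16 named probes of Y-linked genes, 13 were well above background on all 7 arrays other than SIV 3. For 5 of these 13, SIV 3 lay over 4-fold below the lowest of the other 7 arrays. RPS4Y1 was at -0.98 in SIV 3 against 4.3 to 6 elsewhere, RPS4Y2 at -2.38 against 4.14 to 5.4, and EIF1AY at -3.61 against 2.28 to 3.42, on the log2 scale relative to the array's 75th percentile. These genes are in no list and were named after their values were seen. The labels used here give no sex.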
